A study of Mus musculus with 13 samples.

How the data were processed

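RNA from 12 mouse B-cell leukaemias and 1 pool of sorted fetal liver B progenitors was sequenced as paired-end TruSeq stranded mRNA libraries on a HiSeq4000, per the labels' protocols. The design text names cell sorting for the fetal liver cells, and whether the leukaemia samples were sorted is not given in the sources used here. The deposited values are FPKM, which the authors made from reads processed with STAR and Partek against the mm10 build, per the submitters' processing notes. Tool versions, the annotation and the use of strand in counting are not given in the sources used here. The table held 24517 rows for 13 libraries. Of its gene names, 26 had been turned into dates and 2 were repeats, and these were kept under the names given. It holds no mitochondrial genes and no immunoglobulin or T-cell receptor gene segments, so these were not analysed.

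Low values stepped in whole multiples of 1 fragment. Of low values (up to 12 fragments), 73.4 to 76 percent per library were whole fragments, within 0.05 of a whole number, when lengths were taken as the whole gene span, and 9.60 to 10.9 percent when taken as exon length. The deposited FPKM therefore appear to be per kilobase of gene span, introns included, a length that exceeds the exon length by a median ratio of 5.92. Genes with long introns, such as Meis1, Ret and Kit, hence have low values and fell under the filter, while fold changes of a gene between libraries do not depend on its length except through the pseudocount. Spans came from the RefSeq annotation of GRCm38.p6, which covered 96.3 percent of the genes, and coordinates in the text are from it. The same steps gave library depths of 32810000 to 46820000 fragments.

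Libraries were grouped by the titles and genotypes in the labels. The NP23 libraries were numbered in accession order and the RET and E2A-PBX libraries as labelled. Genes with at least 1 FPKM in at least 2 libraries (7762 genes) were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) on log2(FPKM + 1). One fit held the 4 group means over all 13 libraries, so that the fetal liver library, which has no replicate, was assumed to vary like the others. The comparisons were NP23 against the average of the RET and E2A-PBX means, NP23 against each of them, RET against E2A-PBX, and NP23 against fetal liver. p-values were adjusted by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Gene lists (35, of which 31 had at least 3 genes past the filter) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists, tests, comparisons, the rule for named genes and most alternatives were fixed before the data were examined.

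Named genes were those past the threshold whose libraries did not overlap, ranked by absolute log2 fold change. The first 10 per direction were taken for NP23 against both pre-B ALL models and the first 5 for the other comparisons, leaving out unnamed gene models, antigen receptor segments, Xist, Tsix and Y-linked genes. In addition, transgene partners and chosen regulators of B-cell leukaemia were always given, and each list gave up to 4 members with the smallest p. Genes outside this rule are said to be chosen after their values were seen.

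Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, quantile and median-ratio scaling, eBayes without trend and with robust estimation, a fit on the compared libraries alone, pre-B ALL libraries pooled as 1 group, an exact rank-sum test, the adjusted p alone, each leukaemia library left out, and a replicate block. Those added after the data were seen were limma-voom on recovered fragments (at least 1 CPM in at least 2 libraries), the near-identical libraries counted as 1, and fits without those libraries or without the libraries highest in beta-globin. To count the near-identical libraries as 1, RET 2 and RET 3 were averaged as a RET library and the library labelled E2A-PBX 1 was left out. E2A-PBX 2 was then the single E2A-PBX library. The fit was tested on simulated data of 7762 genes with 200 changed, drawn from genes with a mean log2(FPKM + 1) above 2. All libraries were simulated as independent, with 1 SD per gene, so no near-identical libraries were included. The shares recovered need not hold for the real libraries. The highest share of false genes among calls was 6.7 percent, for NP23 against fetal liver at a planted log2 change of 1.5. At a planted log2 change of 1.5 it recovered 87.5 percent for NP23 against both pre-B ALL models, 83 for NP23 against RET, 64.5 for NP23 against E2A-PBX, 60.5 for RET against E2A-PBX and 48.5 for NP23 against fetal liver, and at a log2 change of 3 at least 90.5 percent in each. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.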

Results

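Messenger RNA was sequenced from 12 mouse B-cell acute lymphoblastic leukaemias (ALL) and 1 sample of normal B-cell progenitors, all on the C57BL/6 background. NP23 leukaemias carry a NUP98-PHF23 fusion, which joins a nuclear pore protein to a PHD finger protein, and are described by the labels as progenitor B-1 ALL (7 libraries, 6 from lymph node and 1 from bone marrow). The comparison leukaemias were pre-B ALL of other transgenic models, all from spleen: Eµ-RET (3 libraries), named for the RET receptor tyrosine kinase, and E2A-PBX (2 libraries). The normal sample was wild-type fetal liver cells sorted as Ter119-negative and positive for AA4.1, CD19 and B220, pooled from embryos. No NP23 sample shared a tissue with any other group, so genotype and tissue cannot be told apart in any comparison with NP23. Library depth, recovered from the steps of the low values, ranged from 32810000 to 46820000 fragments, and 5905 to 6396 genes reached 1 FPKM per library. All fold changes below are differences of log2(FPKM + 1) from limma with Benjamini-Hochberg adjusted p, given ± SE, and they understate the change of low genes. A gene passed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The labels give the leukaemias as separate samples without naming animals, so the p-values measure the spread between these samples, each counted as independent.

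The genes named in the transgenes were examined first. Nup98 lay at 0.779 to 1.04 FPKM in the 7 NP23 libraries and at 0.890 to 1.20 in the others, and it did not pass against the pre-B ALL models (-0.07 ± 0.08, adjusted p = 0.529). Phf23 did not pass either (0.00 ± 0.16, adjusted p = 0.996). Ret measured 0.045, 0.098 and 0.102 FPKM in RET 1, RET 2 and RET 3, 0.084 in the library labelled E2A-PBX 1 and 0.001 in E2A-PBX 2. It was at most 0.011 in NP23 and reached 0.139 in wild-type fetal liver, so Ret did not separate the RET libraries from those without the transgene. Pbx1 was at most 0.029 FPKM in all 13 libraries. On recovered fragments, an analysis chosen after the data were seen, limma-voom called Pbx1 higher in NP23 than in pre-B ALL (5.01 ± 1.43, adjusted p = 0.0248) and Ret lower than in RET (-3.75 ± 0.88, adjusted p = 0.0214) and in fetal liver (-4.61 ± 1.03, adjusted p = 0.0419). Whether transgene transcripts map to these mouse genes is not given in the sources used here, so none of these levels checks the labels.

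RET 2, RET 3 and the library labelled E2A-PBX 1 were nearly identical. Their 3 pairwise correlations across genes were 0.9984 to 0.9986, against at most 0.9546 in the other 75 pairs. Their recovered fragments differed by a chi-square of 3.72 to 6.33 per gene, where sampling alone gives about 1 and the other pairs gave at least 129. They differed by more than sampling noise and were kept as separate libraries, but they spanned both labelled genotypes. The SE, SD and p-values with all libraries count them as independent leukaemias, which their closeness puts in doubt. If they are not independent, those SE and p-values are too small. Fits without them leave RET, E2A-PBX and fetal liver with a single library each. The SE, p-values and gene counts of those fits rest on the spread between NP23 libraries alone. Fits that count them as 1 average RET 2 and RET 3 as a RET library. Such fits leave out the library labelled E2A-PBX 1, so E2A-PBX 2 stands alone. RET 2, RET 3 and the library labelled E2A-PBX 1 held little RNA of some other cell types. The complement gene C1qb was at most 0.077 FPKM in them, against 7.25 in RET 1 and 2.59 in E2A-PBX 2. E2A-PBX 2 stood apart in another way, with 3.68 FPKM of the B-cell gene Cd19 against 67.6 ± 8.08 (SD, n = 7) in NP23 and 66.4 ± 27.0 (n = 3) in RET. It also had 112 FPKM of the T-cell gene Thy1 and 9082 FPKM of the beta-globin gene Hbb-b1.

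**Figure D1:**
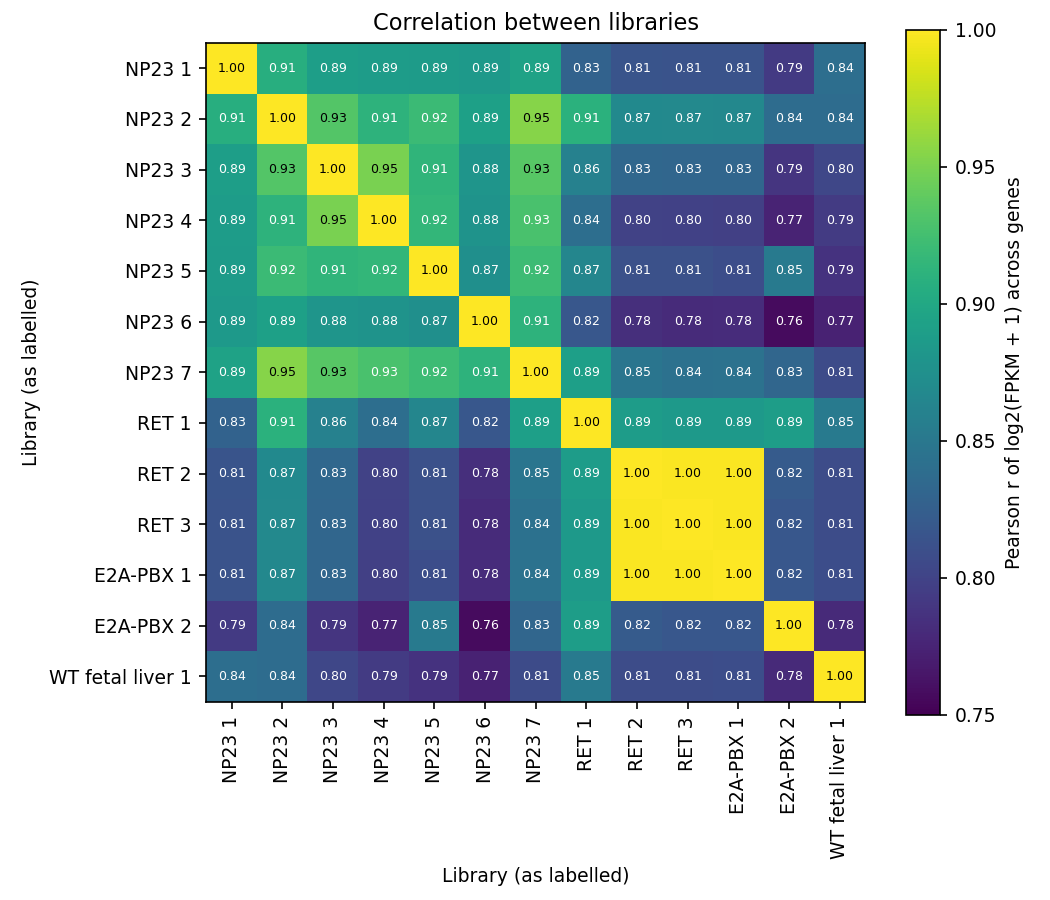
Pearson correlation of log2(FPKM + 1) across genes (colour and printed value, no unit) between each pair of the 13 libraries, which stand on both axes as labelled. RET 2, RET 3 and E2A-PBX 1 correlate at 0.9984 to 0.9986, and every other pair of different libraries at 0.7571 to 0.9546.

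The main comparison asked how NP23 pro-B1 ALL differs from pre-B ALL of both other models. Homeobox genes of the Hoxa cluster, regulators of blood progenitors, were higher in NP23. Hoxa9 (chromosome 6, 52223097 to 52227370, GRCm38) reached 40.3 ± 13.6 FPKM (SD, n = 7) against 0.149 ± 0.089 (n = 5) in pre-B ALL, a log2 fold change of 5.09 ± 0.23 (adjusted p = 5.32e-07). Of 9 tested Hoxa genes, 7 were higher and 0 lower, and 7 were higher when adjusted over the list alone. The list passed (camera adjusted p = 8.60e-09), with adjusted p = 0.124 with an estimated correlation. Hoxa5 rose by 3.32 ± 0.31, Hoxa7 by 3.13 ± 0.29 and Hoxa2 by 1.55 ± 0.12. Mira (chromosome 6, 52214491 to 52215288), a non-coding gene between Hoxa6 and Hoxa7, rose by 4.66 ± 0.25. The spans of Hoxa4, Hoxa5 and Hoxa6 overlap that of Hoxa3, and use of strand in the counting is not given in the sources used here, so their fragments cannot be told apart with certainty. The same holds for Hoxa10, whose span overlaps an unnamed gene model, and for Hoxb4, which overlaps Hoxb3. In the Hoxb cluster, Hoxb4 passed (1.49 ± 0.46, adjusted p = 0.0310) as 1 of 6 tested genes (camera adjusted p = 0.297). Its call was lost without NP23 2, NP23 4, NP23 7, RET 2, RET 3, the library labelled E2A-PBX 1 or E2A-PBX 2 (log2 fold change 1.32 to 1.62, adjusted p = 0.0520 to 0.0888), without a filter and on recovered fragments. Without RET 2, RET 3 and the library labelled E2A-PBX 1 together, the Hoxb list passed with 0 genes past the threshold (median log2 fold change 1.59, camera adjusted p = 0.0297).

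**Figure D2:**
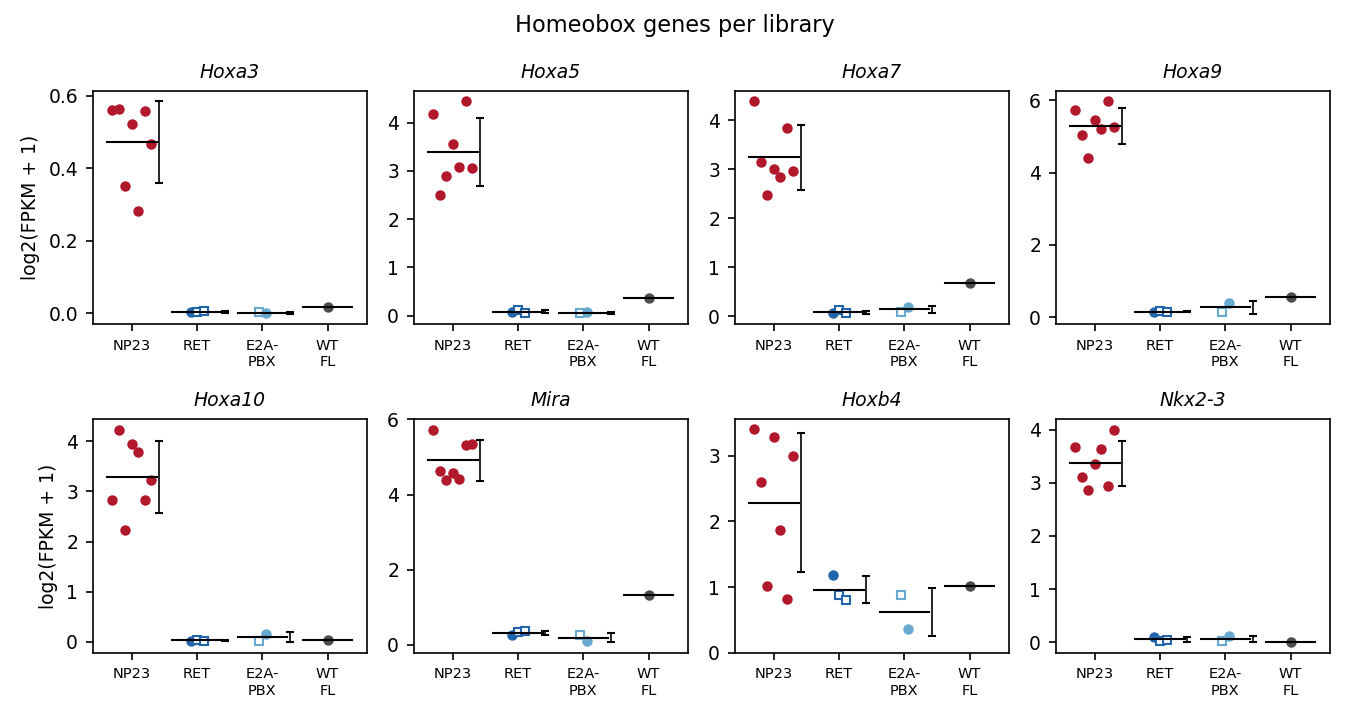
Expression of Hoxa and other homeobox genes and of Mira as log2(FPKM + 1) on the vertical axis, by group on the horizontal axis; each point is 1 library, lines are group means, bars are SD (wild-type, WT FL, has 1 library), and open squares are RET 2, RET 3 and the library labelled E2A-PBX 1. Every NP23 library lies above every pre-B ALL library for Hoxa9 (20.3 FPKM at least, against 0.306 at most) and Nkx2-3 (6.28 against 0.077); Hoxa3 and Hoxa10 were chosen for plotting after their values were seen.

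Nkx2-3, another homeobox gene, stood at 9.73 ± 3.18 FPKM (SD, n = 7) in NP23 and at most 0.077 in pre-B ALL (3.31 ± 0.19, adjusted p = 2.42e-06). With Ly6a (2.73 ± 0.87) it made 2 of 11 stem and progenitor genes higher (camera adjusted p = 0.221). The Ly6a call was lost without NP23 1, NP23 3, NP23 4, NP23 7, RET 2, RET 3 or the library labelled E2A-PBX 1 (log2 fold change 2.09 to 2.74, adjusted p = 0.0524 to 0.148), without a filter and on recovered fragments (adjusted p = 0.0850 and 0.0821). It stood at 0.91 without all the near-identical libraries (adjusted p = 0.555). Meis1, which encodes a DNA-binding partner of HOXA9, has a long span and fell under the filter on low values. It measured 0.298 to 0.602 FPKM in NP23 and at most 0.006 in pre-B ALL. On recovered fragments limma-voom gave Meis1 a log2 fold change of 6.51 ± 0.69 (adjusted p = 5.05e-04). Kit and Flt3 also fell under the filter and did not pass on recovered fragments (adjusted p = 0.201 and 0.657).

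With all libraries, the named gene with the largest rise was Rnase12 (chromosome 14, 51056698 to 51057242), of the ribonuclease A family, at 420.4 ± 204 FPKM (SD, n = 7) in NP23 against 15.4 ± 29.8 (n = 5) in pre-B ALL (6.20 ± 0.74, adjusted p = 3.86e-04). RET 1 held 68.6 FPKM and the other pre-B ALL libraries at most 2.79. Without RET 2, RET 3 and the library labelled E2A-PBX 1 it rose by 4.54 ± 0.53, less than Hoxa9 (5.03 ± 0.37), Mira (4.73 ± 0.39) and Mab21l2 (4.58 ± 0.45), and on recovered fragments Rnase11 (8.18 ± 2.14) and Hoxa9 (8.08 ± 0.80) had larger log2 fold changes than Rnase12 (6.68 ± 1.13). Rnase11 (chromosome 14, 51048693 to 51055702), the neighbour of Rnase12, rose by 3.51 ± 0.47. Mab21l2 (chromosome 3, 86546050 to 86548283), which lies within the span of Lrba, rose by 4.50 ± 0.28. The kinase gene Jak2 rose by 1.31 ± 0.21 and Stat1 passed as well (adjusted p = 0.0231), as 2 of 17 cytokine receptor and JAK-STAT genes (camera adjusted p = 0.492). Of 15 STAT5 targets, the feedback inhibitor gene Socs3 was higher (1.44 ± 0.18) and Myc, Pim1 and Ccnd3 lower (camera adjusted p = 0.680). Cdkn2c, which encodes an inhibitor of cyclin-dependent kinases, rose by 1.82 ± 0.19 and Phlda3 by 1.51 ± 0.21 among 15 DNA damage and p53 genes (camera adjusted p = 0.680). The pro-apoptotic gene Bmf rose by 1.73 ± 0.23 and the polycomb gene Bmi1 by 1.79 ± 0.35, each alone in its list (camera adjusted p = 0.631 and 0.307). With RET 2, RET 3 and the library labelled E2A-PBX 1 left out, Bmi1 (1.41 ± 0.49, adjusted p = 0.0870) and Pim1 (-1.22 ± 0.56, adjusted p = 0.164) did not pass, and DNA damage and p53 genes passed as a list, 4 higher and 1 lower (camera adjusted p = 0.0142). Stat1 and Ccnd3 are named after their values were seen, because they complete small counts.

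The lists of macrophage, stromal and interferon response genes were higher in NP23. Of 18 macrophage and monocyte genes, 12 were higher and 0 lower, 13 when adjusted over the list alone (camera adjusted p = 8.60e-09, and adjusted p = 0.709 with an estimated correlation). C1qc and C1qb, of the complement system, rose by 3.77 ± 0.67 and 3.38 ± 0.59, the adhesion gene Vcam1 by 2.96 ± 0.43 and the lipid transport gene Apoe by 3.78 ± 0.79. Fcna, which overlaps Fcnaos, and Fabp4, both outside the list, rose by 3.52 ± 0.47 and 3.45 ± 0.76. Of 17 endothelial and stromal genes, 6 were higher and 0 lower, 11 when adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.709 with an estimated correlation). The chemokine gene Cxcl12 rose by 2.71 ± 0.42 and the matrix genes Bgn and Sparc by 2.81 ± 0.49 and 2.21 ± 0.58. Of 24 type I interferon response genes, 9 were higher and 0 lower, 11 when adjusted over the list alone (camera adjusted p = 2.49e-06, and adjusted p = 0.709 with an estimated correlation). Irf9 rose by 1.82 ± 0.38, Xaf1 by 1.47 ± 0.33 and Usp18 by 1.39 ± 0.33. Of 5 megakaryocyte and platelet genes, Pf4 (2.31 ± 0.78) and Thbs1 (1.31 ± 0.38) were higher, and the list did not pass (median log2 fold change 1.31, camera adjusted p = 0.240). Pf4 did not pass without NP23 1, NP23 3, NP23 4, NP23 5, NP23 6, NP23 7, RET 2, RET 3 or the library labelled E2A-PBX 1 (log2 fold change 1.87 to 2.46, adjusted p = 0.0522 to 0.157), nor Thbs1 without RET 3 or the library labelled E2A-PBX 1 (1.24 to 1.29, adjusted p = 0.0504 to 0.0747). Neither did so without a filter (adjusted p = 0.0979 and 0.0586), and on recovered fragments Pf4, Fabp4 and Usp18 did not pass (0.0728, 0.101 and 0.147). RET 2, RET 3 and the library labelled E2A-PBX 1 held the lowest C1qb and Apoe of the leukaemias. Without these libraries 2 macrophage, 2 stromal and 0 interferon genes passed, and Apoe (1.90 ± 0.79, adjusted p = 0.132), C1qb (1.95 ± 0.56, adjusted p = 0.0520), Fabp4 (3.28 ± 1.18, adjusted p = 0.0936) and Sparc (2.16 ± 0.90, adjusted p = 0.133) did not, while the lists had camera adjusted p of 4.21e-05, 2.67e-04 and 0.00223.

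**Figure D3:**
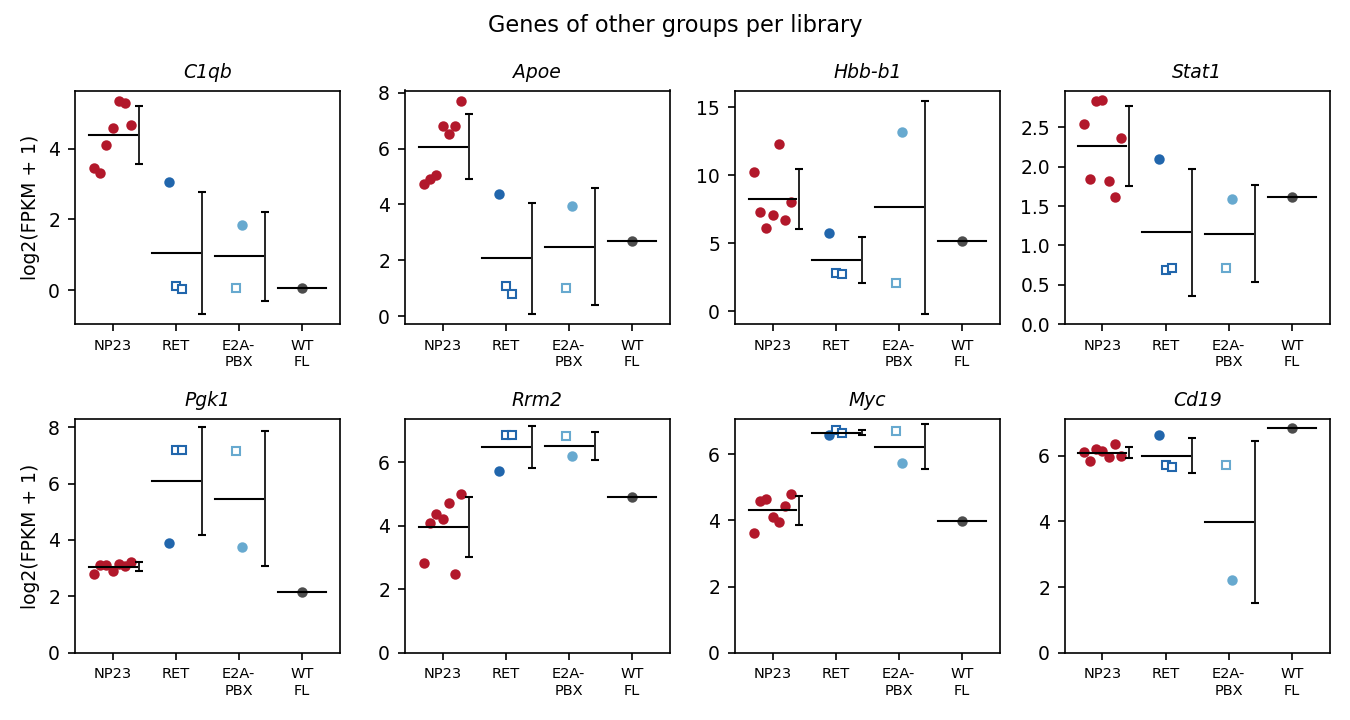
Expression of genes of other groups as log2(FPKM + 1) on the vertical axis, by group on the horizontal axis; each point is 1 library, lines are group means, bars are SD (wild-type, WT FL, has 1 library), and open squares are RET 2, RET 3 and the library labelled E2A-PBX 1. The open squares lie under all other leukaemia libraries for C1qb (at most 0.077 FPKM) and above them for Pgk1 (at least 141 FPKM), and the NP23 libraries lie under all pre-B ALL libraries for Myc; Stat1 was chosen for plotting after its values were seen.

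The lists of cell cycle genes and of MYC and ribosome biogenesis genes were lower in NP23. Of 35 cell cycle genes, 11 were lower and 0 higher, 11 when adjusted over the list alone (camera adjusted p = 9.18e-05, and adjusted p = 0.829 with an estimated correlation). With fry this list did not pass (adjusted p = 0.109). Rrm2, a subunit gene of ribonucleotide reductase, fell by 2.54 ± 0.45, and the replication helicase genes Mcm3 and Mcm4 had log2 fold changes of -1.55 ± 0.28 and -1.23 ± 0.30. Of 22 MYC and ribosome biogenesis genes, 4 were lower and 0 higher, 4 when adjusted over the list alone (camera adjusted p = 3.76e-04, and adjusted p = 0.747 with an estimated correlation). Myc stood at 19.5 ± 5.70 FPKM (SD, n = 7) in NP23 and at least 52.7 in every pre-B ALL library (-2.13 ± 0.25, adjusted p = 3.34e-04). Cad, a gene of pyrimidine synthesis, had a log2 fold change of -1.41 ± 0.20, and Odc1, named after its values were seen, -1.09 ± 0.23. Ldha, of lactate production, was lower too (adjusted p = 0.00287). Pgk1, Aldoa, Tpi1 and Pgam1, each of which encodes an enzyme of glycolysis, were named by their rank, and no list of such genes had been fixed. Tpi1 overlaps Spsb2, so its fragments are uncertain. The log2 fold changes of Pgk1, Aldoa and Pgam1 were -2.72 ± 0.64, -2.57 ± 0.59 and -2.47 ± 0.49, and Tpi1 passed as well (adjusted p = 0.00383). Pgk1 measured 141 to 145 FPKM in RET 2, RET 3 and the library labelled E2A-PBX 1, 13.8 in RET 1, 12.6 in E2A-PBX 2 and 7.31 ± 0.852 in NP23. Without RET 2, RET 3 and the library labelled E2A-PBX 1 none of these 4 genes passed (Pgk1 -0.77 ± 0.18, adjusted p = 0.0290; Tpi1 -1.28 ± 0.44, adjusted p = 0.0831). Neither did Rrm2 (-2.01 ± 0.65, adjusted p = 0.0716), Mcm3 (-1.49 ± 0.44, adjusted p = 0.0557), Mcm4 (-1.12 ± 0.45, adjusted p = 0.124) or Ldha (-1.11 ± 0.33, adjusted p = 0.0594). Then 2 cell cycle and 6 MYC genes were lower, and the cell cycle and MYC lists had camera adjusted p of 0.00630 and 9.06e-07.

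Of the named genes Bex3, an X-linked gene, had the largest fall with all libraries, from 29.0 ± 13.6 FPKM (SD, n = 5) in pre-B ALL to 1.61 ± 1.62 (n = 7) in NP23 (-3.55 ± 0.45, adjusted p = 4.94e-04). Pycr2, of proline synthesis, had a log2 fold change of -2.41 ± 0.21, the granule gene Nkg7 -2.45 ± 0.39 and the tubulin gene Tubb2b -2.20 ± 0.34. Mir6236 (-2.79 ± 0.46) overlaps another gene model, so its fragments are uncertain. The immediate-early genes Jun, Junb and Ier2 were the 3 lower of 12 stress genes (camera adjusted p = 0.155). Under median-ratio scaling Junb (-0.93) and Ier2 (-0.98) fell short of the fold minimum, as they did under quantile scaling, and Junb did so without RET 1 (-0.99) or E2A-PBX 2 (-0.93). Without RET 2, RET 3 and the library labelled E2A-PBX 1, 4 stress genes were lower and the list passed (camera adjusted p = 0.00330). Ier2 and Myc were the 2 lower of 16 MAPK targets (camera adjusted p = 0.503).

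Few genes of early B-cell development passed against pre-B ALL, and some had larger log2 fold changes without RET 2, RET 3 and the library labelled E2A-PBX 1. Of 17 pre-B receptor genes, Cd79b alone passed (1.76 ± 0.40, camera adjusted p = 0.232), and of 10 V(D)J recombination genes the DNA ligase gene Lig4 alone (1.02 ± 0.17, camera adjusted p = 0.155). Lig4 fell short of the fold minimum without NP23 1, NP23 2, RET 2 or the library labelled E2A-PBX 1 (0.94 to 0.98), and the recombination list passed without NP23 6 (camera adjusted p = 0.0476). Cd79b did not pass without the libraries highest in beta-globin, NP23 1, NP23 5 and E2A-PBX 2 (1.09 ± 0.37, adjusted p = 0.0631). The surrogate light chain genes Vpreb1 and Igll1 averaged 689.5 and 252 FPKM in NP23 and did not pass (1.86 ± 0.93 and 2.06 ± 0.83, adjusted p = 0.149 and 0.0794). E2A-PBX 2 held 5.99 and 2.41 FPKM of them. Without the near-identical libraries, which left RET 1 and E2A-PBX 2, the log2 fold changes were 4.45 for Vpreb1, 4.35 for Igll1 and 1.67 for Cd19. The pre-B receptor list then had a median log2 fold change of 0.38, and of 0.82 without the library labelled E2A-PBX 1 alone. Both fits left E2A-PBX 2 as the single E2A-PBX library, so they observed no spread between E2A-PBX libraries. Within NP23, Rag1 ranged from 0.611 to 29.4 FPKM and Dntt from 0.019 to 18.9, and neither passed (adjusted p = 0.325 and 0.436). Cd19, Il7r and Crlf2 did not pass (adjusted p = 0.0932, 0.113 and 0.705). Tcf3, which encodes E2A, had a log2 fold change of -0.78 ± 0.21, short of the fold minimum (adjusted p = 0.0166). None of 18 B-lineage transcription factor genes and none of 15 early B-cell surface markers passed (camera adjusted p = 0.924 and 0.492). Without the near-identical libraries the median log2 fold change of the early B-cell surface markers was 0.40, against 0.43 with all libraries.

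Among genes of later stages, the class II genes H2-Ab1 (-1.34 ± 0.22) and H2-Eb1 (-1.53 ± 0.33) and the chemokine receptor gene Ccr7 (-1.71 ± 0.34) were the 3 lower of 20 later maturation genes (camera adjusted p = 0.873). Without RET 2, RET 3 and the library labelled E2A-PBX 1, Ccr7 (-0.72 ± 0.21, adjusted p = 0.0557) and H2-Ab1 (-1.03 ± 0.29, adjusted p = 0.0507) did not pass. Of 13 fetal and B-1 genes, Hmga1 (-1.64 ± 0.31) and Bhlhe41 (-1.20 ± 0.32) were lower (camera adjusted p = 0.990). Bhlhe41 did not pass without the library labelled E2A-PBX 1 (-0.77 ± 0.30, adjusted p = 0.0866) or with the near-identical libraries as 1 (-0.64 ± 0.29, adjusted p = 0.157). Cd5, a B-1a marker gene that is also in the T-cell list, fell under the filter, with 0.007 to 0.056 FPKM in NP23 and 0.221 to 1.14 in pre-B ALL. For Cd5, limma-voom on recovered fragments gave -4.44 ± 0.67 (adjusted p = 0.00239). Which cells its transcripts came from was not tested. Lin28b was at most 0.024 FPKM in every library, and Bcor did not pass on recovered fragments (adjusted p = 0.197).

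In all, limma called 562 of 7762 genes against pre-B ALL, 325 higher and 237 lower in NP23. Median-ratio scaling, which moved the median log2 fold change of all genes from -0.06 to 0.05, gave 403 higher and 156 lower. The balance turned without RET 2, RET 3 and the library labelled E2A-PBX 1, with 179 higher and 259 lower, and 200 genes were shared with the 562. With those libraries as 1 there were 216 higher and 212 lower. limma-voom on recovered fragments called 2298 of 13110 genes. Besides the lists above, markers of neutrophils, erythroid cells and T cells did not pass (camera adjusted p = 0.973, 0.973 and 0.973), nor did those of plasma cells and dendritic cells (0.221 and 0.924). Without a filter the lists of T-cell, stress, trithorax and polycomb, and PRC1.1 and BCOR complex genes passed (camera adjusted p = 0.0143, 0.0375, 0.0234 and 0.00821), and the last also on recovered fragments (0.0285). The plasma cell list passed without the library labelled E2A-PBX 1 (0.0482). Without the near-identical libraries, neutrophil genes were lower as a list (median log2 fold change -2.11, camera adjusted p = 1.73e-06), with 8 of 13 past the threshold, and erythroid genes likewise (-1.56, adjusted p = 0.00264, 1 past the threshold). Without E2A-PBX 2 erythroid genes were instead higher (2.39, adjusted p = 0.00562). Of 62 genes examined singly that had passed, 29 no longer passed without RET 2, RET 3 and the library labelled E2A-PBX 1. Of the 6 lists called of 31, none passed with an estimated correlation and 5 passed with fry. fry, which asks whether the genes of a list move one way without setting them against other genes, called 11 lists in all. Those without a camera call were stem and progenitor genes (fry adjusted p = 3.63e-05), V(D)J recombination (0.0485), trithorax and polycomb regulators (0.0289), MAPK targets (0.0485), plasma cell genes (0.0389) and stress genes (0.0274).

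**Figure D4:**
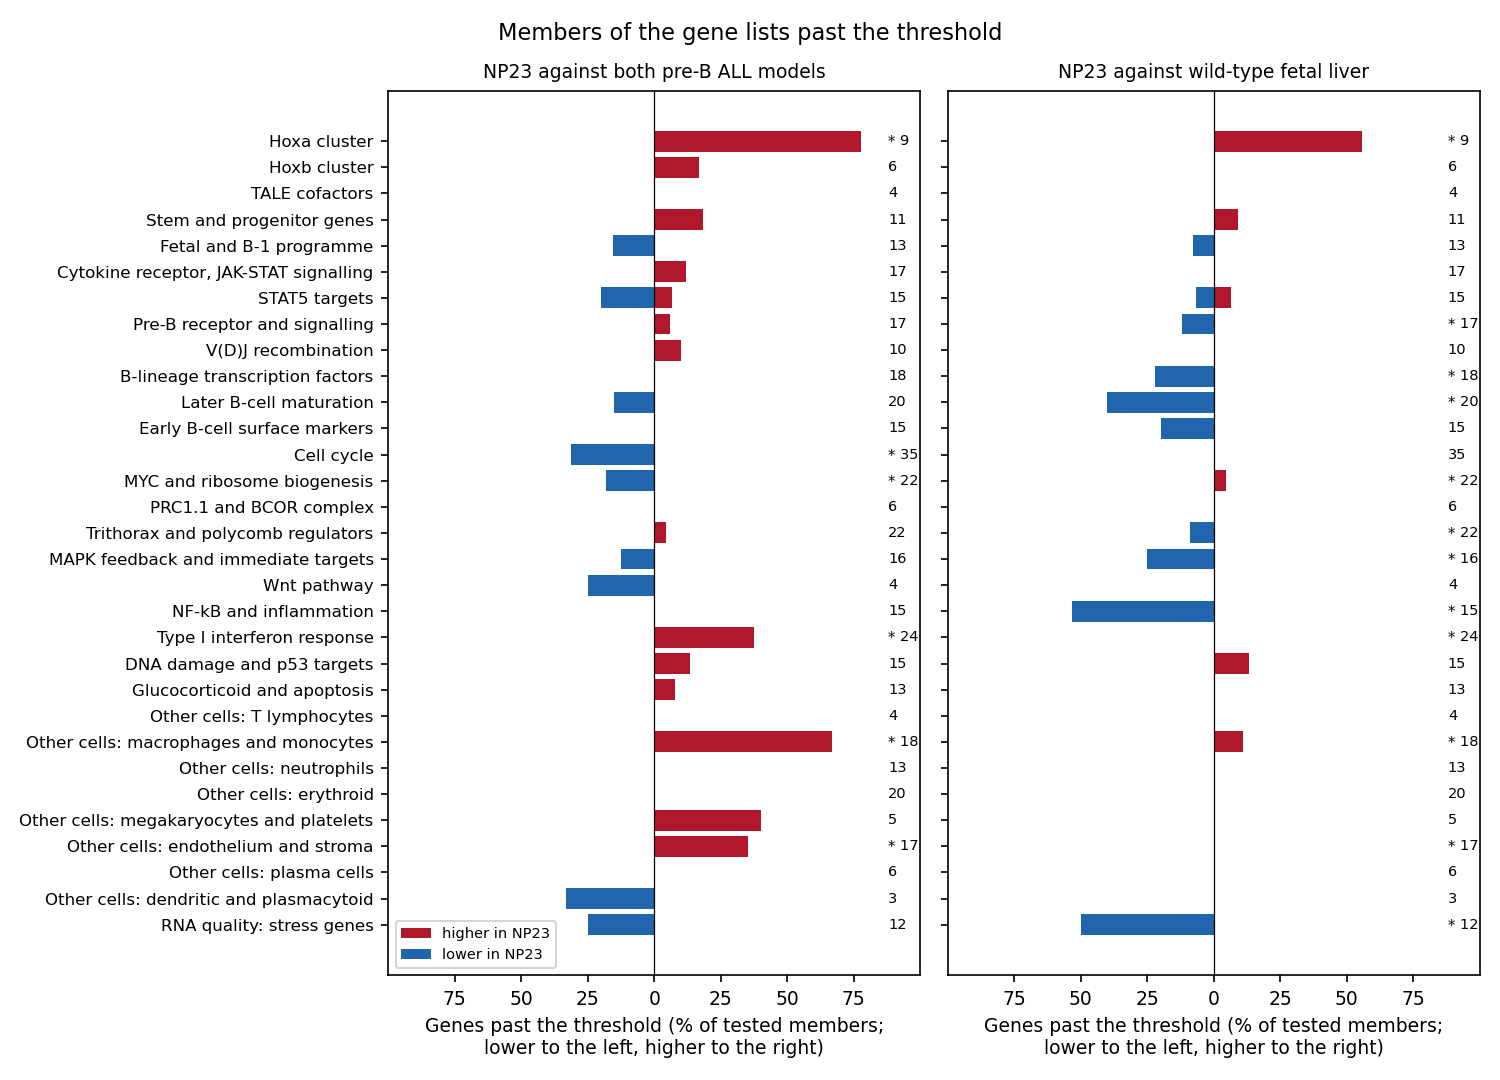
Share of the tested members of each gene list past the threshold, in percent on the horizontal axis (higher in NP23 to the right, lower to the left), against both pre-B ALL models and against wild-type fetal liver. The numbers give the tested members and asterisks a camera adjusted p under 0.05; 7 of 9 Hoxa genes were higher against pre-B ALL, and 8 of 20 later B-cell maturation genes were lower against fetal liver.

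Against RET alone, NP23 was again higher in Rnase12 (5.53 ± 0.87), Hoxa9 (5.15 ± 0.27, adjusted p = 2.69e-06), Mira (4.59 ± 0.29), Mab21l2 (4.51 ± 0.33) and Apoe (3.99 ± 0.92). It was lower in Bex3 (-3.39 ± 0.52), Pgk1 (-3.04 ± 0.74), Aldoa (-2.85 ± 0.69), Eno1b (-3.06 ± 0.68), a near-identical copy of the glycolytic gene Eno1 whose fragments are uncertain, and Cox6a2 (adjusted p = 0.00925), which overlaps Itgad. Without RET 2 or without RET 3, Pgk1 (adjusted p = 0.0920 to 0.0963), Aldoa (0.0891 to 0.0961), Eno1b (0.0646 to 0.0700) and Apoe (0.0755 to 0.0757) did not pass, nor did Cox6a2 without RET 2 (0.0512). Tcf3 was lower as well (-1.06 ± 0.24, adjusted p = 0.0127), but fell short of the fold minimum with quantile (-0.90) and median-ratio scaling (-0.88) and without NP23 6 (-0.99) or RET 1 (-0.93), and did not pass without RET 2 (adjusted p = 0.0541). Of Hoxa genes 7 of 9 were higher, also when adjusted over the list alone (camera adjusted p = 1.96e-09, and adjusted p = 0.0992 with an estimated correlation). Of macrophage genes 11 of 18 were higher, 12 when adjusted over the list alone (camera adjusted p = 7.42e-09, and adjusted p = 0.630 with an estimated correlation). Of interferon genes 8 of 24 were higher, 11 when adjusted over the list alone, and of stromal genes 3 of 17, Cxcl12, Bgn and Sparc, 6 when adjusted over the list alone (camera adjusted p = 1.26e-07 and 3.01e-05, and adjusted p = 0.630 for each with an estimated correlation). Of cell cycle genes 6 of 35 were lower, 7 when adjusted over the list alone, and of MYC genes 3 of 22, Myc, Cad and Ldha, also when adjusted over the list alone (camera adjusted p = 2.20e-04 and 1.81e-04, and adjusted p = 0.729 and 0.630 with an estimated correlation). limma called 495 genes, 268 higher and 227 lower, and median-ratio scaling gave 343 higher and 131 lower. The count was 199 without RET 2 and 226 without RET 3. A fit without all the near-identical libraries left RET 1 as the single RET library, assumed to vary like the NP23 libraries. In that fit Rnase12 (2.44 ± 0.71, adjusted p = 0.101), Bex3 (-1.98 ± 0.66, adjusted p = 0.135), Apoe (1.70 ± 1.05, adjusted p = 0.370) and Tcf3 (adjusted p = 0.0812) did not pass. Neither did Pgk1 (-0.84), Aldoa (-0.96), Eno1b (-1.37) and Cox6a2 (-2.68), with adjusted p = 0.0611 to 0.285. The balance of calls turned in that fit (42 higher and 72 lower), with the near-identical libraries as 1 (124 higher and 135 lower), with a filter of 5 FPKM (166 higher and 198 lower), and without NP23 7 (241 higher and 276 lower), RET 2 (99 higher and 100 lower) or RET 3 (111 higher and 115 lower). On recovered fragments Meis1 was higher (6.28 ± 0.83, adjusted p = 0.00293) and Cd5 lower (-3.92 ± 0.73, adjusted p = 0.0111). In that fit 2 of 25 interferon and 0 of 23 stromal genes were higher, with 10 of 22 macrophage and 8 of 10 Hoxa genes. The interferon and stromal lists still passed there (camera adjusted p = 1.44e-04 and 4.85e-04). Of the 6 lists called, 3 passed with fry, which also called stem and progenitor genes (fry adjusted p = 5.52e-05), trithorax and polycomb regulators (0.0223), MAPK targets (0.0223), Wnt pathway genes (0.0302) and stress genes (0.0270).

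Against the libraries labelled E2A-PBX, NP23 was higher in Rnase12 (6.86 ± 1.01), Hoxa9 (5.03 ± 0.32, adjusted p = 1.91e-05), Mira (4.72 ± 0.33), Mab21l2 (4.49 ± 0.39) and Rnase11 (3.80 ± 0.64). It was lower in Bex3 (-3.71 ± 0.60), Mir6236 (-2.83 ± 0.62), Pycr2 (-2.57 ± 0.29), Rrm2 (-2.55 ± 0.61) and the class I histocompatibility gene H2-Q2 (-2.78 ± 0.53), one of a family of similar genes whose fragments are uncertain. H2-Q2 measured 15.1 FPKM in E2A-PBX 2 and 2.17 in the library labelled E2A-PBX 1. Of Hoxa genes 7 of 9 were higher, also when adjusted over the list alone (camera adjusted p = 2.07e-09, and adjusted p = 0.10 with an estimated correlation). Of macrophage genes 7 of 18 were higher, 12 when adjusted over the list alone, of stromal genes 2 of 17, Cxcl12 and Bgn, and of interferon genes 0 of 24 (camera adjusted p = 2.75e-08, 1.36e-04 and 1.36e-04, and adjusted p = 0.750 for each with an estimated correlation). Lower were 4 of 35 cell cycle genes, Rrm2, Mcm3, E2f1 and Ccne1, and 4 of 22 MYC genes, Myc, Cad, Odc1 and Ldha (camera adjusted p = 1.36e-04 and 0.00205, and adjusted p = 0.826 and 0.750 with an estimated correlation). Pre-B receptor genes were higher as a list, with Cd79b and Vpreb3 past the threshold of 17 tested (camera adjusted p = 0.00447, and adjusted p = 0.750 with an estimated correlation), beside the low Cd19 of E2A-PBX 2. limma called 308 genes, 174 higher and 134 lower, and median-ratio scaling gave 241 higher and 97 lower. The count was 80 without E2A-PBX 2 and 197 without NP23 4. The balance turned on recovered fragments (162 higher and 230 lower), without all the near-identical libraries (152 higher and 187 lower) or with them as 1 (142 higher and 189 lower), and without NP23 7 (171 higher and 191 lower), the library labelled E2A-PBX 1 (188 higher and 241 lower) or E2A-PBX 2 (39 higher and 41 lower). Without NP23 3 there were 145 higher and 88 lower and without NP23 4 115 higher and 82 lower. On recovered fragments Meis1 was higher and Cd5 lower (adjusted p = 0.0159 and 0.00958). In that fit 4 of 10 Hoxa, 0 of 22 macrophage and 0 of 23 stromal genes were higher. Lower were 0 of 35 cell cycle and 2 of 23 MYC genes, while each of these lists still passed with camera. Without E2A-PBX 2, H2-Q2 (-1.62 ± 0.50, adjusted p = 0.105) and Rnase11 (3.86 ± 0.88, adjusted p = 0.0590) did not pass, and Mir6236 and Rrm2 did not without either E2A-PBX library (adjusted p = 0.0766 to 0.0937 and 0.0921 to 0.133). On recovered fragments Rnase12, Rnase11, Rrm2 and H2-Q2 did not pass (adjusted p = 0.0516 to 0.133), nor did Mir6236 and Rrm2 without a filter (0.0502 and 0.0660). Without the libraries highest in beta-globin (NP23 1, NP23 5 and E2A-PBX 2), 7 of the 10 genes named first no longer passed (adjusted p = 0.0553 to 0.151). That fit left a single E2A-PBX library, assumed to vary like the other groups, and the log2 fold changes were 7.16 for Rnase12, 4.12 for Rnase11, -4.32 for Bex3, -2.77 for Mir6236, -2.67 for Pycr2, -2.79 for Rrm2 and -1.62 for H2-Q2. Of the 7 lists called, 1 passed with fry, which also called stem and progenitor genes (fry adjusted p = 4.94e-04).

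Between the pre-B ALL models, RET and E2A-PBX, limma called 0 genes, with 78 at an unadjusted p under 0.05 and 0 called by limma-voom on recovered fragments. Vpreb1, Igll1 and Cd19 averaged 599.7, 160.0 and 66.4 FPKM in RET and 424, 110.5 and 27.7 in E2A-PBX, without passing. As lists, pre-B receptor genes (median log2 fold change 1.16, camera adjusted p = 2.12e-12), B-lineage transcription factors (0.37, adjusted p = 1.12e-04) and MAPK targets (0.29, adjusted p = 0.0118) were higher in RET, with adjusted p = 0.200, 0.282 and 0.296 with an estimated correlation. Erythroid genes (-2.12, adjusted p = 9.46e-20), the 4 T-cell genes tested (-1.71, adjusted p = 4.24e-07) and interferon genes (-0.08, adjusted p = 0.00873) were lower, with adjusted p = 0.282, 0.200 and 0.788 with an estimated correlation. None of these 6 lists passed with fry. E2A-PBX 2 held the highest Hbb-b1 and Thy1 and the lowest Cd19 of all libraries. Without the library labelled E2A-PBX 1, which was nearly identical to RET 2 and RET 3, 218 genes passed, with E2A-PBX 2 assumed to vary like the other groups.

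Compared with normal fetal liver B progenitors, the list of Hoxa genes was higher in NP23, and the lists of later B-cell maturation, B-lineage transcription factor and stress genes were lower. Hoxa9 rose by 4.75 ± 0.42 (adjusted p = 1.49e-04), from 0.466 FPKM in the fetal liver library, Hoxa10 by 3.27 ± 0.56 and Nkx2-3 by 3.36 ± 0.34. Of 9 Hoxa genes 5 were higher, 7 when adjusted over the list alone (camera adjusted p = 4.81e-07, and adjusted p = 0.0604 with an estimated correlation). The calls of Hoxa2, Hoxa5 and Hoxa10 were lost on recovered fragments, at log2 fold changes of 4.06 ± 1.16, 4.95 ± 2.12 and 8.60 ± 3.36. In the fit on FPKM Rnase12 rose by 6.26 ± 1.34 and Mab21l2 by 4.45 ± 0.51, and Cdkn2c, Phlda3 and Socs3 by 1.84 ± 0.34, 2.04 ± 0.37 and 1.55 ± 0.33. On recovered fragments Phlda3 and Socs3 did not pass (adjusted p = 0.210 and 0.0725), nor did Socs3 in a fit on the compared libraries alone (0.0503), while Meis1 was higher (3.49 ± 0.80, adjusted p = 0.0464) and Bcor lower (-1.38 ± 0.32, adjusted p = 0.0480). Fcna rose by 4.30 ± 0.85 but did not pass on recovered fragments (adjusted p = 0.302), and C1qb and Vcam1 were the 2 macrophage genes past the threshold of 18, 10 when adjusted over the list alone (camera adjusted p = 1.66e-06, and adjusted p = 0.439 with an estimated correlation). C1qb did not pass without NP23 2, NP23 3, NP23 4, NP23 5, NP23 6, NP23 7, RET 2 or RET 3 (adjusted p = 0.0514 to 0.0706), nor Vcam1 without NP23 3 (0.0527), and neither did without a filter (0.0750 and 0.0519) or on recovered fragments (0.380 and 0.281). The fetal liver cells had been sorted, and C1qb was 0.053 FPKM in them. Of 20 later maturation genes 8 were lower, 11 when adjusted over the list alone (camera adjusted p = 2.49e-12, and adjusted p = 0.0515 with an estimated correlation). Fcmr, the IgM receptor gene, fell by 3.42 ± 0.37, Ms4a1, which encodes CD20, had a log2 fold change of -3.84 ± 0.47 and H2-Ab1 -3.12 ± 0.40. Of 18 B-lineage transcription factors 4 were lower, Klf2 (-4.44 ± 0.72), Ikzf3 (-2.14 ± 0.47), Bach2 (-1.52 ± 0.28) and Foxo1 (-1.41 ± 0.34), and 9 when adjusted over the list alone (camera adjusted p = 4.34e-07, and adjusted p = 0.0604 with an estimated correlation). Foxo1 did not pass without NP23 2, NP23 4, NP23 5, NP23 6, NP23 7, RET 2 or RET 3 (adjusted p = 0.0553 to 0.0720). On recovered fragments Ikzf3, Bach2 and Foxo1 did not pass (adjusted p = 0.167, 0.221 and 0.105), and at pseudocounts of 0.1 and 0.5 Ikzf3 and Foxo1 did not. The signalling genes Blk (-2.64 ± 0.36) and Pik3ap1 (-1.13 ± 0.25) were the 2 lower of 17 pre-B receptor genes, 4 when adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.506 with an estimated correlation). Ly6d (-5.49 ± 1.24), Cxcr4 (-1.97 ± 0.26) and Ptprc (-1.93 ± 0.35) were the 3 lower of 15 early B-cell surface markers (camera adjusted p = 0.136). Pik3ap1 did not pass without NP23 3, NP23 4 or NP23 5 (adjusted p = 0.0502 to 0.0548), nor Ly6d without NP23 2, NP23 3 or NP23 5 (0.0534 to 0.0579) or without a filter (0.0564). On recovered fragments Pik3ap1 and Ptprc did not pass (0.122 and 0.0630). With a filter of 5 FPKM the pre-B receptor list did not pass (camera adjusted p = 0.0753).

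Fos and Jun, immediate-early genes, had the largest falls of the genes named against fetal liver, before Ly6d. Fos stood at 197 FPKM in fetal liver and 0.728 to 2.03 in the 7 NP23 libraries (-6.60 ± 0.65, adjusted p = 2.83e-04), and Jun at 242 and 0.881 to 3.09 (-6.31 ± 0.48). Junb and Klf4 had log2 fold changes of -4.55 ± 0.39 and -4.46 ± 0.32. Of 12 stress genes, which can respond to cell sorting and handling, 6 were lower, also when adjusted over the list alone (camera adjusted p = 5.53e-07, and adjusted p = 0.0515 with an estimated correlation). Of 15 NF-kB and inflammation genes 8 were lower, 10 when adjusted over the list alone, among them Tnfaip3 (-3.39 ± 0.37) and Cd69 (-4.44 ± 0.55) (camera adjusted p = 9.47e-10, and adjusted p = 0.0515 with an estimated correlation). Of 16 MAPK targets 4 were lower, Fos, Ier2, Dusp5 and Egr1, 5 when adjusted over the list alone (camera adjusted p = 0.00857, and adjusted p = 0.272 with an estimated correlation). Of 22 trithorax and polycomb genes 2 were lower, Cbx7 (-1.73 ± 0.34) and Kmt2b (-1.14 ± 0.28) (camera adjusted p = 0.00190, and adjusted p = 0.153 with an estimated correlation). Kmt2b lay at the threshold and did not pass without NP23 2, NP23 3, NP23 4, NP23 5, NP23 6, NP23 7, RET 2, RET 3, the library labelled E2A-PBX 1 or E2A-PBX 2 (adjusted p = 0.0534 to 0.0763), at other pseudocounts and filters or with robust estimation, and Cbx7 did not at a pseudocount of 0.1 (0.0602) or on recovered fragments (0.0976). MYC genes were higher as a list with Npm1 (1.70 ± 0.42) past the threshold, and stromal and interferon genes as lists with 0 (camera adjusted p = 0.0417, 0.00582 and 0.0173, and adjusted p = 0.770, 0.635 and 0.770 with an estimated correlation). Npm1 did not pass without NP23 2, NP23 3, NP23 4, NP23 5, NP23 7, RET 2, RET 3, the library labelled E2A-PBX 1 or E2A-PBX 2 (adjusted p = 0.0504 to 0.0751) or in a fit on the compared libraries alone (0.0900). The MYC list did not pass without NP23 2, NP23 6 or NP23 7 (camera adjusted p = 0.0584 to 0.0804), and Egr1 did not without NP23 3 (0.0524). With a filter of 5 FPKM none of the trithorax and polycomb, MYC, stromal and interferon lists passed (camera adjusted p = 0.0694, 0.208, 0.0694 and 0.307), and the interferon list did not on recovered fragments (0.0955). None of 35 cell cycle genes passed (camera adjusted p = 0.712). limma called 237 genes, 92 higher and 145 lower, with the single fetal liver library assumed to vary like the other groups. The count was 439 without NP23 1, 153 without NP23 5 and 155 without RET 3. There were 53 higher and 125 lower without NP23 2, 49 higher and 111 lower without NP23 3, 42 higher and 111 lower without NP23 5, 40 higher and 119 lower without RET 2 and 37 higher and 118 lower without RET 3. The balance of calls turned without NP23 1 (239 higher and 200 lower), at a pseudocount of 0.1 (171 higher and 112 lower) and with a filter of 5 FPKM (101 higher and 63 lower). Recovered fragments gave 41 higher and 249 lower. Of 43 genes examined singly that had passed, 18 no longer passed on recovered fragments, among them Rnase12, Hoxa10, Nkx2-3 and Mab21l2 (adjusted p = 0.101 to 0.227), and 13 at a pseudocount of 0.1, among them Blk, Ms4a1, Ly6d, Bach2, C1qb, Vcam1 and Pik3ap1 (adjusted p = 0.0541 to 0.128). Of the 12 lists called, 7 passed with fry, which also called early B-cell surface markers (fry adjusted p = 0.0187).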

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

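These values were found by a search over 83 named genes in the 7 NP23 libraries for a library far from the others, and no test of a cause was run. A library is listed when its gap to the nearest other exceeds 0.568 of the whole range, which chance gives in about 5 percent of genes, so 2 of 83 is no more than chance gives. Mir6236 measured 32.9 FPKM in NP23 3, against 2.82 to 6.89 in the other NP23 libraries. Rag1, a gene of V(D)J recombination, measured 0.611 FPKM in NP23 6, against 8.22 to 29.4 in the others.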

How the results depend on the processing

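The settings with limma-voom on recovered fragments, with the near-identical libraries as 1, and without those libraries or those highest in beta-globin were chosen after the data were seen. Of named-gene results against both pre-B ALL models across the alternatives, 3350 kept their side of the threshold, 123 newly passed and 116 no longer passed. Of list results there, 798 kept their side, 25 newly passed, 7 no longer passed and 2 reversed. Against fetal liver 800 list results kept their side, 5 newly passed and 26 no longer passed. A change of direction was counted only where a result passed in at least 1 of the compared fits. What depth limits here was not tested against the number of libraries.

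Leaving out 1 leukaemia library at a time gave 464 to 655 genes against both pre-B ALL models, 199 to 659 for NP23 against RET (lowest without RET 2, highest without RET 1), 80 to 429 against E2A-PBX (lowest without E2A-PBX 2, highest without the library labelled E2A-PBX 1), 0 to 218 for RET against E2A-PBX (highest without the library labelled E2A-PBX 1) and 153 to 439 against fetal liver (lowest without NP23 5, highest without NP23 1). A library left alone in its group was assumed to vary like the others. A pseudocount of 0.1 gave 1185, 1010 and 653 genes against both models, RET and E2A-PBX, and 0.5 gave 476 against E2A-PBX. Without a filter 329 passed against RET and 157 against E2A-PBX, where more genes were tested. The adjusted p alone, a looser rule, passed 2292, 1633 and 714. limma-voom on recovered fragments, which tested 13110 genes and puts a lower floor under low values, gave 2298 against both models and 1291 against RET. Counting the near-identical libraries as 1 gave 259 against RET, 65 for RET against E2A-PBX and 151 against fetal liver, and leaving them out gave 114 against RET and 22 for RET against E2A-PBX. Without the libraries highest in beta-globin (NP23 1, NP23 5 and E2A-PBX 2) 21 passed against E2A-PBX. Against fetal liver, quantile scaling gave 361 and a fit on the compared libraries alone 146; the cause was not tested. The erythroid list reversed against both pre-B ALL models, from a median log2 fold change of -0.48 (adjusted p = 0.973) to 2.39 without E2A-PBX 2, the library with the most beta-globin (adjusted p = 0.00562), and 2.97 without the libraries highest in beta-globin; it was -1.34 without the library labelled E2A-PBX 1.

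RET and E2A-PBX share the replicate numbers 1 and 2, which the labels tie to no animal, batch or day, so the samples share only a number. Deviations of same-numbered samples correlated at -0.629 and -0.616, but with a pair of E2A-PBX libraries these deviations mirror each other, so the check is void. With the replicate block 1 gene passed between RET and E2A-PBX, against 0 without it.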

Other observations

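The values in this part on homeobox genes within NP23 and on E2A-PBX 2, and the tests of the near-identical libraries, of the glycolytic genes, of dilution and of splits with those libraries as 1, were chosen after the results were seen. Hoxa11 and Hoxb6 differed between NP23 libraries, while Hoxa9 was at least 20.3 FPKM in each. Hoxa11 measured 7.55 FPKM in NP23 2, 2.55 in NP23 4 and 3.02 in NP23 5, and at most 0.430 in the other NP23 libraries. Hoxb6 measured 14.2 to 21.8 FPKM in NP23 1, NP23 2 and NP23 7 and at most 2.99 in the other NP23 libraries, and 2.87 to 3.07 in RET 2, RET 3 and the library labelled E2A-PBX 1. Hoxa11 overlaps Hoxa11os and Hoxb6 overlaps Hoxb5os, and use of strand is not given, so these fragments are uncertain. Dntt, the terminal transferase gene, measured 18.9 FPKM in NP23 4 and at most 3.91 in the other NP23 libraries.

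E2A-PBX 2 held transcripts of several lineages. The T-cell genes Lat and Lck measured 32.2 and 9.91 FPKM there, against at most 12.2 and 2.63 in the other libraries, and the erythroid regulator gene Gata1 8.77 against at most 3.73. Camp, a neutrophil granule gene, measured 31.7 FPKM in E2A-PBX 2 and 62.1 in RET 1. Hbb-b1 reached 4959 FPKM in NP23 5 and 1184 in NP23 1, the bone marrow sample.

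RET 2, RET 3 and the library labelled E2A-PBX 1 were nearly identical. Separate leukaemias that happen to look alike are argued against by a highest chi-square per gene of 6.33 among these libraries, under the lowest of the 21 NP23 pairs (129). A single library whose deposits differ by counting error alone is argued against by a lowest chi-square per gene of 3.72, where sampling alone gives about 1. That bound covers counting error only, so a library prepared or run again with other technical differences cannot be told apart. A mislabelled sample stays open: Ret at 0.084 FPKM in the library labelled E2A-PBX 1 lay within the RET range, but Ret was higher still in fetal liver, so it cannot decide. Several samples of the same leukaemia, or of a transplanted line, could also look like this, which was not tested. Since the libraries carry both genotype labels, that account would itself put at least 1 label in doubt. The comparisons with RET and with E2A-PBX, and between them, rest on these labels.

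The macrophage and stromal lists were higher in NP23 with camera at the preset correlation, but did not pass with an estimated correlation (camera adjusted p = 0.709 for each). Over the NP23 libraries the macrophage list had a mean pairwise correlation of 0.586 (at most 0.383 in 1000 random lists) and the stromal list 0.543 (at most 0.294). Differing amounts of such cells in these samples would give this, but so could other lists of genes used together. The cell cycle list, which marks no cell type, had a higher estimated correlation in camera (0.82) than the macrophage list (0.636). The covariation also lies within NP23, so it does not address the difference from pre-B ALL. The lists share 0 and 0 genes with other lists, and 3 of 18 macrophage and 2 of 17 stromal genes reached 1 FPKM in the near-identical libraries. The share of the difference set by those libraries cannot be told apart: without them the macrophage median was 1.04 (bootstrap SE 0.24, over genes) against 1.84, too close to the bound of 1 set beforehand. Tissue and genotype stay open and untested, as does any sort of the leukaemia samples.

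The cell cycle list was lower in NP23, as were Pgk1, Aldoa, Tpi1 and Pgam1, enzyme genes of glycolysis picked by rank with no list fixed. The cell cycle median was -0.68 (bootstrap SE 0.15) without the near-identical libraries and -0.79 with them, so the list was lower also against RET 1 and E2A-PBX 2. That SE resampled genes, not libraries, so it does not measure the spread between leukaemias. With so few libraries left, the share of the difference set by the near-identical libraries cannot be told apart. The 4 glycolysis genes had a median of -1.01 without those libraries against -2.53 with them, and Pgk1 -0.77 against -2.72. Much of their difference with all libraries therefore came from the near-identical libraries. What remains rests on RET 1 and E2A-PBX 2. Dilution of NP23 by RNA of other cells cannot be told apart. It would lower early B-cell surface markers with the cell cycle list, and their median was 0.43 (bootstrap SE 0.33, over genes), with 8 of 15 above 0, but -0.04 (SE 0.42) without the library labelled E2A-PBX 1. The marker median was 0.28 (SE 0.15) without E2A-PBX 2, 0.40 (SE 0.43) without the near-identical libraries and 0.05 (SE 0.41) with them as 1. In each setting it lay above the cell cycle median, which was -0.88 to -0.66, but not always clearly above 0. Slower division of NP23 leukaemias and tissue stay open and untested.

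Other splits of the same libraries were counted for the comparisons with at least 3 libraries on each side. In NP23 against both pre-B ALL models, 1 of 100 splits, the real one, gave as many genes (562, highest other 205), and in NP23 against RET 1 of 100 (495, highest other 15). The near-identical libraries stay together in the real grouping, while other splits can part them, so the splits were repeated with them as 1, which leaves RET with a pair of libraries. The real split alone then gave as many genes, of 100 splits against both models and of 36 against RET. In both comparisons, however, the highest count of any other split came nearer to the real count than with all libraries. With 36 splits the smallest possible share is 1 of 36, and E2A-PBX is left with a single library. These splits therefore make chance less likely for both counts but cannot exclude it.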
